A study of Homo sapiens with 4 samples.

How the data were processed

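RNA-seq was performed on total RNA of MDA-MB-468 cells extracted with TRIzol, with libraries made by an NEBNext Ultra RNA kit, per the labels' protocols. The 4 libraries were grouped by their titles into 2 shControl and 2 shSASH1 libraries, and each value column carries the name of 1 library. The deposited values are TPM per Ensembl gene, a unit of transcript abundance that divides reads by gene length and scales each library to a common total, so a rise of abundant transcripts lowers the others. STAR, DESeq2 and hg38 are listed in the submitters' processing notes without versions or roles. The read counter, the gene annotation, the gene lengths behind TPM and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The rows analysed summed to 924683, 926711, 922024 and 910830 TPM.

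All 26518 gene identifiers were found in GENCODE release 29 on hg38, 18999 of them protein-coding, and 25647 had a current symbol. Coordinates are 1-based positions from that annotation. TPM keeps no depth, so read numbers were rebuilt from TPM times the exon-union length in GENCODE, with a scale per library that made low values whole. Of values of up to 20 reads, 89.1%, 89.1%, 89.0% and 88.5% came within 0.05 of a whole number. The rebuilt totals of 20806828, 24204187, 24383873 and 19566651 reads are estimates, since the authors' gene lengths may differ. The chi-square per degree of freedom between replicates on these reads was 2.26 in shControl (14579 genes) and 25.8 in shSASH1 (14514 genes). The shControl pair thus differed by more than counting noise, and was kept as 2 samples.

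Genes with a mean of at least 1 TPM over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with lmFit and eBayes with a variance trend, without a block for replicate number, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The moderated variance had 2.54 prior degrees of freedom. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so gene-level inference relies on limma's model. Gene lists were tested with camera with a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 3 tested members out of 35, and again with an estimated correlation, under which 0 of 31 passed. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries rather than from the genes. The EGFR and ERK list had an estimated correlation of -0.000441, below the preset one, yet its unadjusted camera p went from 4.4e-05 to 0.0438. The 0 of 31 therefore cannot tell genes that vary together from so few degrees of freedom. The result of 1 list that passed with the preset correlation, and some named genes, are not reported here. The 29 pathway lists and 6 cell-type lists, the test, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule named SASH1, ARHGAP42, YAP1, CCN1 and CCN2, then the 10 higher and 10 lower genes with the largest absolute log2 change among those past the threshold without overlap of the groups and with a group mean of at least 5 TPM. It left out pseudogenes and unnamed loci, and added up to 4 called members per list and the 3 most abundant markers per cell-type list. Other genes, such as KRT5, KRT17, KLK5, KLK7, GADD45A and NT5E as list members, ACTB, S100A7, DSC3 and KRT6A, were named after their values were seen.

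Tested on 5 simulated data sets of this comparison with 200 changed genes and a mean of 14453.2 genes, the procedure recovered 57.4% of genes changed by 1 log2 unit and 82.2% of those changed by 2, with a false share of 3.72% and 0 unchanged lists called. The simulated noise was independent between genes and of equal SD in both groups. The simulation therefore cannot test camera on genes that vary together. In the data the estimated inter-gene correlation was 0.84 in the antigen presentation list. A wider spread in shSASH1 and changes in many more genes were not simulated either. Windows of 20 Mb with at least 20 tested genes were compared with 1000 shuffles of gene positions. The settings fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, 2 other variance models, a replicate block, each library left out, an absolute log2 change of at least 1 and the estimated correlation. Chosen after seeing the data were voom on rebuilt reads, a length and GC correction, centring on windows, leaving out genes under 300 exon bases, leaving out mitochondrially encoded genes, and a separate spread per group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation and plots.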

Results

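Gene expression was measured by RNA-seq in MDA-MB-468, an established human cell line from a triple-negative breast cancer, which lacks estrogen and progesterone receptors and HER2 amplification. Cells carried a lentiviral short hairpin RNA against SASH1, a scaffold protein with SAM and SH3 domains, or a control vector, and were selected with puromycin as stable lines. There were 2 libraries of control cells (shControl) and 2 of SASH1-depleted cells (shSASH1). The values were TPM, transcript abundance scaled for gene length and library size, for 26518 Ensembl genes, of which 14458 had a mean of at least 1 TPM and were tested. Read numbers rebuilt from the TPM values came to 20806828 and 24204187 for the shControl libraries and 24383873 and 19566651 for the shSASH1 libraries. Pearson's correlation of log2(TPM + 1) across genes was 0.988 between the shControl libraries, 0.975 between the shSASH1 libraries and 0.924 to 0.942 between groups, and principal component 1 held 76.6% of the variance. Genes are not independent replicates. The median within-group SD was 0.0507 log2 units in shControl and 0.126 in shSASH1. The labels do not say whether the 2 libraries of a group came from separate cultures, or how many clones or hairpins they represent, so the p-values measure only the spread between these samples, which may be technical.

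The comparison asked how depletion of SASH1 changes the transcriptome. SASH1 (chromosome 6, 148272304 to 148552050, hg38, plus strand, protein-coding) stood at 15 and 13 TPM in the shControl libraries and at 3.65 and 4.01 TPM in the shSASH1 libraries. It fell from a mean of 14 ± 1.38 TPM to 3.83 ± 0.257 TPM (SD, n = 2 per group), a ratio of means of 3.66, with a log2 change of -1.63 ± 0.13 (SE) and limma adjusted p = 0.00391. CCN1 (chromosome 1, 85580761 to 85583962), a secreted matricellular protein and a standard YAP target, rose from 31.5 ± 0.636 to 263 ± 73.6 TPM, or 8.35-fold (log2 change 2.99 ± 0.20, adjusted p = 0.00301). CCN2 (chromosome 6, 131948176 to 131951373), its relative, rose 2.76-fold from 6.38 ± 1.19 to 17.6 ± 2.53 TPM (log2 change 1.34 ± 0.17, adjusted p = 0.00921). ARHGAP42 (chromosome 11, 100687653 to 100993941), a GTPase-activating protein, rose from 0.0757 ± 0.0035 to 3.27 ± 0.33 TPM (log2 change 1.99 ± 0.21, adjusted p = 0.00631); its control level rests on 4 and 5 rebuilt reads. YAP1 itself (chromosome 11, 102110461 to 102233423), the transcriptional coactivator restrained by the Hippo kinases, was at 101 ± 0.527 TPM in shControl and 117 ± 5.10 TPM in shSASH1 and did not pass (log2 change 0.21 ± 0.06, adjusted p = 0.0621). Without shControl replicate 1 SASH1 did not pass (log2 change -1.54, adjusted p = 0.0927), nor did it without shControl replicate 2 (-1.73, adjusted p = 0.0941), because the spread then comes from the shSASH1 pair alone. Log2 changes are on the log2(TPM + 1) scale throughout, which understates the change of low genes.

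**Figure D1:**
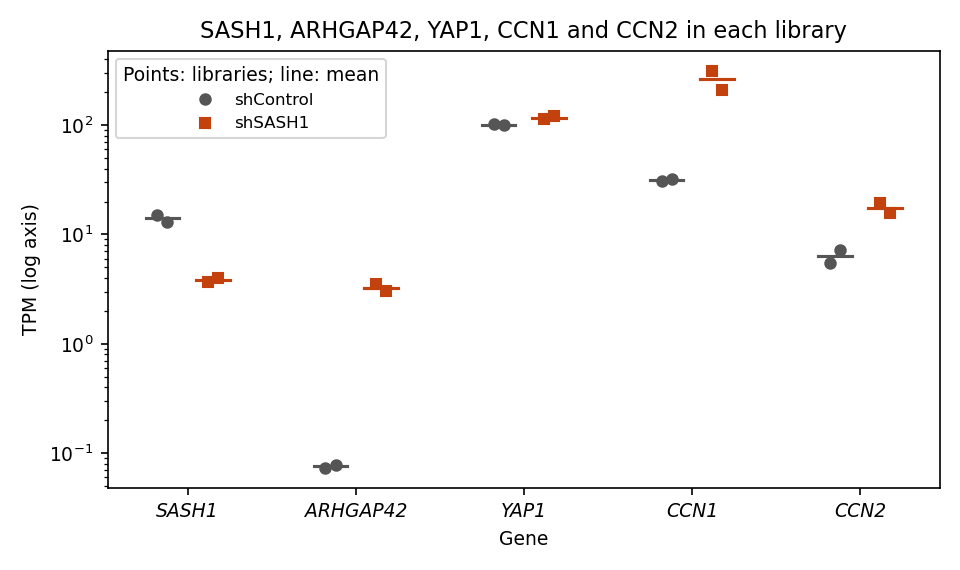
TPM on a log axis for SASH1, ARHGAP42, YAP1, CCN1 and CCN2. Each point is a library, circles for shControl and squares for shSASH1, and the line is the mean of 2 libraries; SASH1 lies at 13 to 15 TPM in shControl and 3.65 to 4.01 TPM in shSASH1.

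Across the transcriptome, 4630 of 14458 genes passed, 2712 higher and 1918 lower in shSASH1, and 9828 did not. Among the genes with the largest rise, OLFM4, a secreted glycoprotein of intestinal crypts, went from 14.2 ± 1.18 to 717 ± 52.8 TPM (log2 change 5.57, adjusted p = 0.00117). SH3BGRL, a small SH3-binding protein, was at 0.0679 TPM (2 rebuilt reads in the 2 shControl libraries) and 79.9 ± 2.08 TPM. The others were the neurofilament gene NEFH (log2 change 4.55), the neutrophil chemokine CXCL1 (4.42, with 17.9 and 52.9 TPM in the shSASH1 libraries), the protease inhibitor TFPI2 (4.38), prostacyclin synthase PTGIS (4.38), PLXDC2 (4.22), SPATC1L (4.15), FTHL17 and ZNF711 (4.03). FTHL17 was listed at 0 in both shControl libraries and at 22 and 10.9 TPM in shSASH1, and as a ferritin heavy chain copy it may share reads with its relatives. In the other direction, the kallikrein-related peptidase KLK6 fell from 703 ± 11 to 12.6 ± 8.97 TPM (log2 change -5.87, adjusted p = 0.004) and the calcium-binding protein CALB2 from 40.6 ± 2.41 to 0.101 ± 0.016 TPM (-5.24, adjusted p = 0.00151). KLK8 (-5.06), STAC2 (-4.65), the folate receptor FOLR1 (-4.65), slow skeletal troponin T TNNT1 (-4.47), PALM (-4.33), TBATA (-4.02), the transcription factor TWIST2 (-3.87) and the CD47 receptor SIRPA (-3.83) completed the 10 with the largest fall among genes of at least 5 TPM in 1 group. With an absolute log2 change of at least 1 as well, 734 genes were higher and 554 lower. The groups did not overlap for 73.6% of tested genes, against 33.3% by chance. The higher share of calls was 58.6%, but 50.1% after the length and GC correction (2325 higher, 2314 lower), 48.4% after quantile normalization (2280 higher, 2434 lower) and 47.4% with voom on rebuilt reads (2534 higher, 2812 lower). Leaving out a library leaves 1 in its group, so the spread then comes from the other group's pair alone. That spread was narrow in shControl and wider in shSASH1 (median within-group SD 0.0507 and 0.126 log2 units). Without either shControl library no gene passed limma's threshold, and without a shSASH1 library more genes passed than in the main test. These numbers follow the spread used and do not show which calls rest on a given library.

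In the Hippo pathway and YAP/TAZ target lists the genes that passed all rose. Of 19 tested YAP/TAZ target genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 change of 0.62. Beside CCN1 and CCN2 these included CCDC80 (2.37), the muscle ankyrin repeat gene ANKRD1 (1.94), GADD45A (1.16) and the ecto-nucleotidase NT5E (1.15). Among 24 Hippo pathway components, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.36. PTPN14 (1.05) and NF2 (0.95), which restrain YAP, rose, as did the YAP paralog WWTR1 (0.84) and its DNA-binding partner TEAD1 (0.83). Both lists passed camera's competitive test (adjusted p = 0.000196 and 0.00169), and each had adjusted p = 0.586 with an estimated correlation. Of the 13 target genes called, 6 lay in chromosome windows that were shifted as a whole, described further on. With genes centred on their windows, GADD45A had a log2 change of 0.68, PTPN14 0.64 and WWTR1 0.60, the last no longer passing (adjusted p = 0.0587). Within shSASH1, replicate 2 lay below replicate 1 in 14 of 19 target genes, by a median of -0.22.

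Of the actin genes that passed, nearly all rose. The actin cytoskeleton list had 19 of 44 members higher and 1 lower (20 and 4 adjusted over the list alone), with a median of 0.23. Tropomyosin TPM2 rose from 17.1 ± 0.764 to 212 ± 17.8 TPM (log2 change 3.55), myosin light chain MYL9 rose by 3.06 from a near-absent control level (1 rebuilt read), and talin TLN1 rose by 1.93 and the actin bundler PLS3 by 1.5. Of the 20 called actin genes 5 lay in windows shifted as a whole, and with genes centred on their windows TPM2 had a log2 change of 2.46, TLN1 0.83 and PLS3 0.80. ACTB was not called, at 3470 ± 117 TPM in shControl and 3165 ± 1347 TPM in shSASH1, and 36 of the 44 actin genes were lower in shSASH1 replicate 2 than in replicate 1, by a median of -0.15. Camera's adjusted p was 0.0238 for the actin list (adjusted p = 0.674 with an estimated correlation). Of 23 TGF-beta targets, 10 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0463, adjusted p = 0.586 with an estimated correlation). The adhesion scaffold NEDD9 (3.61) and TSPAN2 (2.11) rose, while the basement membrane collagen COL4A1 (-2.17) and the BMP-responsive regulator ID1 (-2.07) fell. SMAD4, reported as deleted in this line, was at 0.352 TPM in shControl and 0.202 TPM in shSASH1, and TGF-beta signalling was not measured. Without shSASH1 replicate 1 neither list passed (adjusted p = 0.247 for actin, with a shift from other genes of 0.20 against 0.34, and 0.0762 for TGF-beta). The TGF-beta list also missed the threshold without shControl replicate 1 (0.0545), without shSASH1 replicate 2 (0.0760), after quantile normalization (0.0576) and without a variance trend (0.0540), and the actin list with a mean TPM of at least 5 (0.0539).

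In the interferon, antigen presentation and NF-kB lists the genes that passed were all higher in shSASH1. Of 38 type I interferon response genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 0.49. IFIT2 (2.86), IFI44 (2.42), IFIT3 (2.36) and the ubiquitin-like modifier ISG15 (2.15) led, ISG15 going from 25.5 ± 1.89 to 117 ± 2.23 TPM. Of 18 antigen presentation genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.86. HLA-B rose from 145 ± 10.8 to 497 ± 192 TPM (1.72), and HLA-F (1.76), the lysosomal protease CTSS (1.57) and the immunoproteasome subunit PSMB9 (1.26) rose as well. Of 31 NF-kB targets and cytokines, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.86. Beside CXCL1 these included the apoptosis inhibitor BIRC3 (3.06), the chemokine CXCL8 (2.97) and the adhesion molecule ICAM1 (2.95, from 18.4 ± 0.752 to 153 ± 53.9 TPM). The 3 lists passed camera (adjusted p = 3.1e-05, 3.1e-05 and 0.000136), and each had adjusted p = 0.60 with an estimated correlation. The same lists differed between the shSASH1 libraries. Replicate 2 lay above replicate 1 in 30 of 38 interferon, 18 of 18 antigen presentation and 29 of 31 NF-kB genes, by medians of 0.33, 0.39 and 0.50. Reads of HLA and IFIT genes can be shared between near copies, which makes the single values uncertain.

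In the list of EGFR and ERK outputs the genes that passed all rose. Of 29 members, 15 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.66 and camera adjusted p = 0.000196 (adjusted p = 0.586 with an estimated correlation). EGFR itself, which is amplified in this line, rose from 1122 ± 66.9 to 2197 ± 8.69 TPM (log2 change 0.97), with PHLDA1 (1.65), cyclin D1 CCND1 (1.5) and the ETS factor ETV4 (1.03). In the immediate early and AP-1 list 5 of 24 rose and 3 fell (10 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.338). There EGR3 (-2.45) and EGR1 (-2.33) fell while ATF3 (1.90) and KLF6 (1.26) rose.

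Of the basal keratinocyte-type markers that passed, nearly all fell. Of 22 tested, 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median log2 change of -1.36, camera adjusted p = 7.1e-07 and adjusted p = 0.586 with an estimated correlation. The fall took in KLK5 (-1.82), KLK6, KLK7 (-3.35), KLK8 and KLK10 (-3.65), the surface protein LY6D (-3.80), S100A7 (-2.93) and the desmosomal cadherin DSC3 (-2.39), and KRT6A rose (0.92). The abundant basal keratins did not pass: KRT5 was at 1056 ± 9.26 TPM in shControl and 991 ± 331 TPM in shSASH1, and KRT17 at 465 ± 0.759 and 394 ± 236 TPM. Within shSASH1, replicate 2 lay below replicate 1 in 18 of the 22 markers, by a median of -0.57. Of 14 luminal breast markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.358), with KIT (-1.80), SPDEF (-1.39) and GATA3 (-0.49) lower and AGR2 (0.90) higher.

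In the nuclear and mitochondrial lists of oxidative phosphorylation genes the members that passed were all lower. Of 41 nuclear-encoded oxidative phosphorylation genes, 20 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.27, camera adjusted p = 4.7e-06 and adjusted p = 0.586 with an estimated correlation. UQCRC1 of complex III fell from 254 ± 9.23 to 118 ± 2.16 TPM (-1.10), and NDUFB9 (-0.99, or -0.67 centred on its window), COX6C (-0.91) and cytochrome c1 CYC1 (-0.76, or -0.35 centred on its window) fell too. Of the 13 mitochondrially encoded genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.0118, adjusted p = 0.60 with an estimated correlation), including MT-CO3 (-0.95) and MT-ND3 (-0.70). These 13 genes took 14.9% and 14.8% of the TPM in the shControl libraries and 13.3% and 11.5% in the shSASH1 libraries. After quantile normalization the list did not pass (camera adjusted p = 0.853), its shift from other genes going from -0.40 to -0.04. That setting gives the highest ranks the same values in each library, so it can hide a fall shared by such abundant genes. Without a filter it did not pass either (0.0556), with a shift of -0.38. Cytosolic ribosomal proteins had a median of -0.15, with 7 of 44 lower and 5 higher (7 and 5 adjusted over the list alone; camera adjusted p = 0.000799, adjusted p = 0.60 with an estimated correlation). RPL28 (-0.63) fell, and RPL37 (0.53; 0.11 centred on its window, adjusted p = 0.171) and RPLP1 (0.46) rose. Of 37 G2/M and mitosis genes, 4 fell and 1 rose (2 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 0.00756, adjusted p = 0.689 with an estimated correlation). The spindle and motility gene HMMR (-1.11), the phosphatase CDC25B (-0.93) and the checkpoint kinase TTK (-0.41) fell and the kinesin KIF23 (0.68) rose. Of the 5 called G2/M genes 4 lay in windows shifted as a whole. Centred on their windows, CDC25B had a log2 change of -0.45 and still passed, while HMMR (-0.84, adjusted p = 0.0702) and TTK (-0.06, adjusted p = 0.550) did not. The G2/M list did not pass without shSASH1 replicate 2 (adjusted p = 0.190), its shift from other genes going from -0.28 to -0.07, and replicate 2 lay below replicate 1 in 36 of 37 members, by a median of -0.29.

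**Figure D2:**
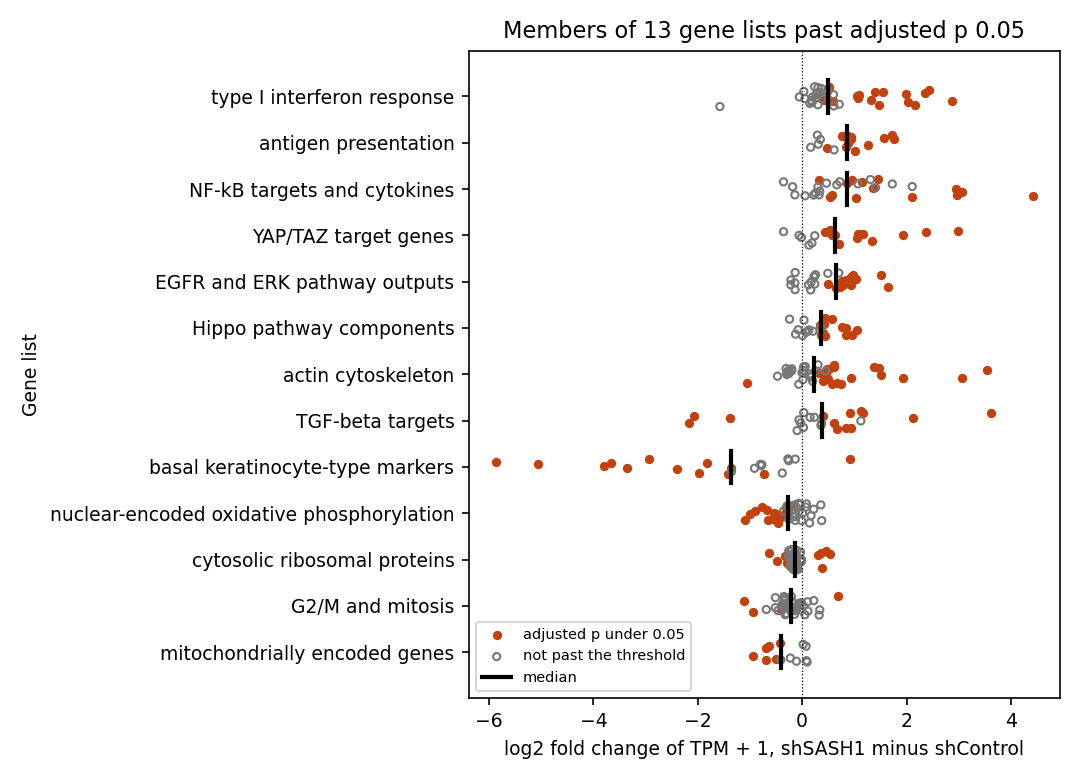
Log2 fold change of TPM + 1, shSASH1 minus shControl, for each tested member of 13 of the 14 lists past camera's adjusted p of 0.05. Filled points are genes past adjusted p 0.05, open points the rest, and the bar is the list's median, from 0.86 for NF-kB targets and cytokines to -1.36 for basal keratinocyte-type markers.

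The remaining lists did not pass camera. In the mesenchymal transition list 7 of 19 rose and 2 fell (12 and 3 adjusted over the list alone; adjusted p = 0.0546), with LGALS1 (2.14) and vimentin VIM (2.15, from 0.679 to 6.91 TPM) higher, TWIST2 lower, and TWIST1 higher after being listed at 0 in both shControl libraries. Integrins and focal adhesion genes had 14 of 30 higher and 3 lower (15 and 4 adjusted over the list alone; adjusted p = 0.0614), including FERMT2 (1.75), ITGA2 (1.45) and ITGB6 (1.40). The matrix and proteolysis list had 10 of 29 higher and 7 lower (12 and 8 adjusted over the list alone; adjusted p = 0.465), with the laminin chain LAMB3 (1.89) higher. Among epithelial junction genes 7 of 35 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.175), and claudin CLDN1 rose from 10 ± 0.512 to 99.6 ± 15.5 TPM. PI3K-AKT and FOXO output had 10 of 26 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0546), among them KLF6 and the transcription factor FOXO1 (1.13). In the p53 target list 6 of 25 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.193), with TP53I3 (-1.81) lower and GADD45A higher. Apoptosis regulators had 11 of 30 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0719), among them TNFSF10 (1.28) and MCL1 (0.85, or 0.52 centred on its window). The unfolded protein list had 8 of 32 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.139), with PPP1R15A (1.10) and DNAJB9 (1.05) higher. Hypoxia and glycolysis genes had 7 of 29 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.142), with ADM (2.15) and HIF1A (0.93) higher. Of 36 G1/S genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone; adjusted p = 0.707), CDK6 (1.62) up and UHRF1 (-1.20) down. Of 31 cholesterol and fatty acid genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.866), ELOVL6 (3.42) up and EBP (-1.26; -0.37 centred on its window, adjusted p = 0.136) down. Of 18 replication-dependent histone genes, whose near-identical copies make reads uncertain, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.327), but the list passed with a mean TPM of at least 5 (adjusted p = 0.00807), its shift from other genes going from 0.18 to 0.99. In the list of the SASH1 family and described partners, SASH1 fell and CRKL (0.37) and IQGAP1 (0.33) rose among 15 members (1 and 2 adjusted over the list alone; adjusted p = 0.798). Without shSASH1 replicate 2 the mesenchymal (adjusted p = 0.0145), integrin (0.0181), epithelial junction (0.0407) and PI3K-AKT (0.0407) lists passed, and the mesenchymal list also passed without shControl replicate 1 (0.0229) or replicate 2 (0.0212). The mesenchymal list passed after median-of-ratios scaling (0.0369) and quantile normalization (0.0226) too, and its adjusted p ran from 0.0145 to 0.0452 over all settings in which it passed. Without a filter the integrin (0.0265), PI3K-AKT (0.0229) and apoptosis (0.0380) lists passed, with voom the integrin (0.0461) and PI3K-AKT (0.0398) lists, and after centring on windows the integrin (0.0151), PI3K-AKT (0.0109) and unfolded protein (0.0390) lists did.

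Markers of other cell types were few and mostly low. Of 3 macrophage markers 0 passed (0 adjusted over the list alone; adjusted p = 0.723), with CD14 at 36.5 ± 4.70 TPM in shControl and at 33.3 and 96.5 TPM in the shSASH1 libraries. The log2 change of CD14 was 1.38 without shSASH1 replicate 1 and -0.13 without replicate 2, so its rise rests on 1 library. Of 3 endothelial markers ESAM fell (-0.94) and 2 did not pass (the same count adjusted over the list alone; adjusted p = 0.338). For the other lists only 2 members each were tested and no list test was run. FAP fell (-1.18) and COL1A1 was at 6.66 and 9.92 TPM among fibroblast markers (1 higher and 1 lower adjusted over the list alone). IL7R rose (0.88; 0.38 centred on its window, adjusted p = 0.191) among lymphocyte markers, and LTB, at 0.871 TPM in shControl and 9.34 ± 9.14 TPM in shSASH1, did not pass (2 higher adjusted over the list alone). Neither adipocyte marker passed over all genes or adjusted over the list alone, PLIN1 being at 4.03 and 2.75 TPM. Neither HEK293-type marker passed over all genes, and 1 was lower adjusted over the list alone, with UCHL1 at 10.3 and 8.76 TPM and WT1 at 10.4 and 7.88 TPM.

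Whole chromosome regions moved together. Among 152 windows of 20 Mb with at least 20 tested genes, 25 had a median log2 change farther from the genome median of 0.06 than 0.312, the 95th percentile of the largest departure in 1000 shuffles of genes, 13 of them higher and 12 lower. The strongest was chromosome 9 from 20 to 40 Mb, with a median of 1.10 over 97 genes, 60 higher and 5 lower, where TPM2, TLN1 and CA9 lie. Windows on chromosome 1 from 60 to 100 Mb (0.48 and 0.40), which holds CCN1, and from 160 to 260 Mb (0.37 to 0.61) were higher, as were chromosome 2 from 220 to 240 Mb (0.56) and chromosome 5 from 20 to 60 Mb (0.50 and 0.42). On X, windows from 0 to 60 Mb were lower (-0.63, -0.45 and -0.88) and those from 100 to 140 Mb higher (0.70 and 0.47). Lower windows also lay on chromosome 5 from 160 to 180 Mb (-0.26), on chromosome 6 from 80 to 120 Mb and 140 to 180 Mb (-0.32 to -0.38), on chromosome 8 from 100 to 160 Mb (-0.32 to -0.42) and on chromosome 20 from 0 to 20 Mb (-0.49). SASH1 lies in the chromosome 6 window from 140 to 160 Mb, whose median was -0.38, and with each gene centred on its window its log2 change was -1.26 (adjusted p = 0.0079). The largest departure between replicates was 0.0504 in shControl and 0.129 in shSASH1. The shifted windows held 951 of the 4630 calls (20.5%), against 12.2% of tested genes, and 881 of the 951 had their window's direction. After centring, 3720 genes passed, 3152 of them calls of the main test with the same sign (68.1%), and genes that no longer passed included WWTR1, F11R, HMMR, TTK, ATF6, CA9, EBP, RPL37 and IL7R.

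**Figure D3:**
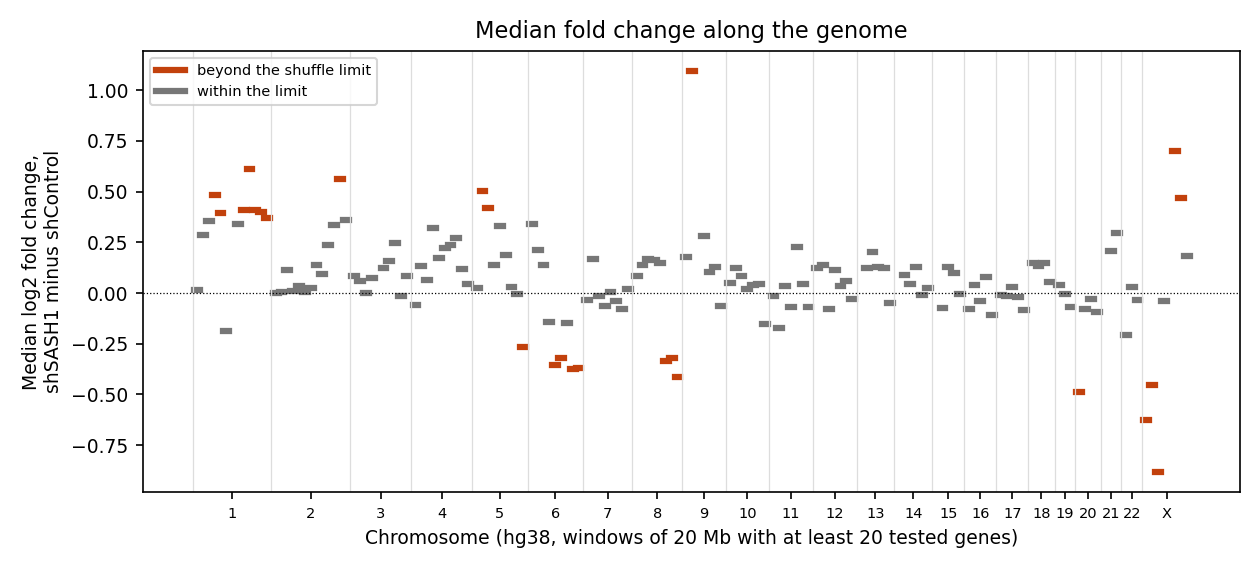
Median log2 fold change, shSASH1 minus shControl, of the tested genes in each 20 Mb window of hg38 with at least 20 genes, ordered along the chromosomes. Coloured bars are the 25 windows beyond the shuffle limit, the highest at 1.10 on chromosome 9 and the lowest at -0.88 on X.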

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

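The alternatives chosen after seeing the data were voom on rebuilt reads, the length and GC correction, centring on windows, leaving out short or mitochondrially encoded genes, and a separate spread per group. SASH1 stayed lower under every alternative run, and passed under all but those leaving out a shControl library; over the 4 libraries left out in turn its log2 change ran from -1.73 to -1.54. Counts over these 4 ran from 0 to 4562 higher and from 0 to 3245 lower, the 0 values coming without either shControl library (3462 and 3359 genes at an unadjusted p under 0.05), where the lone control is assumed to vary like the shSASH1 pair. With an absolute log2 change of at least 1 the counts were 734 and 554, by construction. With an estimated correlation, a setting that also leaves camera few degrees of freedom, 0 lists were higher and 0 lower, against 9 and 5. The mean correlation between groups moved from 0.933 to 0.890 with a pseudocount of 0.1, 0.967 without a filter and 0.912 with a mean TPM of at least 5; the filters change which genes enter.

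Among named genes and lists, signs turned only for those not called in the main test, while centring on windows turned the sign of 180 other calls. For lists the sign is camera's direction, which can differ from the sign of the shift in mean log2 change. The cholesterol list had a median of -0.05, a mean of 0.15, a shift of 0.0784 and a downward camera direction. That direction was upward without a filter (shift 0.103) and without a variance trend (the same shift of 0.0784). Its shifts ran from -0.101 to 0.27 over the libraries left out. The SASH1 partner list had a median of 0.16, a mean of -0.02, a shift of -0.0918 and an upward camera direction. That direction was downward after quantile normalization (shift -0.106) and the length and GC correction (-0.126). Its shifts ran from -0.113 to -0.0678 over the libraries left out. The G1/S list, with a median of -0.07 and a mean of 0.06, had 0.050 after centring and -0.0301 to 0.0116 over the libraries left out. CSF1R had -0.0303 with median-of-ratios, -0.0486 with quantile, -0.00647 with voom and -0.00272 without mitochondrially encoded genes. Over the libraries left out CSF1R ran from -0.50 without shSASH1 replicate 1 to 0.54 without shSASH1 replicate 2. PLIN4 had 0.00128 after the length and GC correction and -0.36 to 0.33 over the libraries left out, and CD14 -0.13 to 1.38. The cause was not tested.

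The labels do not say whether replicate numbers pair the samples, and the correlation of same-numbered deviations was -0.03. With the replicate block SASH1 had -1.63, and 2372 genes were higher and 1557 lower, 3678 of these 3929 shared with the main calls. Depth is limited by TPM, from which reads were rebuilt: genes under about 1 TPM were not tested, and levels resting on 0 to 5 reads, as for SH3BGRL, ZNF711 or ARHGAP42 in shControl, have wide counting error.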

Other observations

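The tests weighed here were chosen after the data were seen. The bounds for the segment, the contiguous deletion and the centring of the oxidative phosphorylation list were written after their results were seen, and those for the other cell line, the share of calls in shifted windows and the length and GC correction before. The families and genes here were also chosen after their values were seen. Of 6 tested kallikrein genes 5 were lower, with a median log2 change of -3.50. The 5 are those already counted among the basal markers, and KLK6, KLK8 and KLK10 lie between 50958631 and 51020175 on chromosome 19. Of 14 tested S100A genes 6 were lower and 2 higher, with a median of -0.75. Of 5 classical and related HLA class I genes 4 were higher, with a median of 0.93. The NKG2D ligand MICB rose from 14.1 ± 0.261 to 163 ± 26.3 TPM, and complement C3 from 5.94 ± 0.847 to 87.0 ± 56.5 TPM (limma adjusted p = 0.00156 and 0.0105). Between the 2 shSASH1 libraries, which compares 1 library with 1, the median of replicate 2 minus replicate 1 was set against 10000 random lists of the same size and like expression. It lay at percentile 0 for the G2/M (-0.29), basal (-0.57) and cholesterol (-0.28) lists, at 0.01 for the YAP/TAZ and actin lists and at 100 for the interferon, antigen presentation and NF-kB lists, so many lists differed between these libraries. Some lists were also extreme between the 2 shControl libraries, mostly at smaller medians. There the G1/S list lay at percentile 0.07 (-0.04) and the replication-dependent histones at 99.92 (0.14).

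A set of 41 genes had a mean under 0.5 TPM in shControl and at least 5 TPM in shSASH1, and 8 of them lie on X, which holds 3.06% of tested genes. They include SH3BGRL, HMGN5, ZNF711 and CYSLTR1, and the reverse set of 39 genes has 4 on X; of these sets 10 and 7 are miRNA precursors (0 and 1 on X), which are so short that few reads give a high TPM. The counts were noticed in the data and include neighbouring genes, so no p-value is given. A candidate explanation for 3 of the 8 genes on X is a segment that differs in copy number or silencing between the cell populations. In their window, X from 80 to 100 Mb, the 5 other tested genes had a median log2 change of 0.76 (0.17 to 1.82). Among these 5, POF1B was itself at 0 TPM in shControl. RADX and RNF128 lie from 100 to 120 Mb (window median 0.70) and an unnamed locus from 120 to 140 Mb (0.47). FTHL17 lies in a window that was lower (-0.45), so it does not go with a higher segment. CYSLTR1 lies near the end of a window at -0.04. The tested gene before it, TAF9B, had a log2 change of -0.09 and the next, BRWD3 in the window from 80 Mb, 0.76. Whether CYSLTR1 belongs to a higher segment is therefore not settled. A single contiguous deletion from HMGN5 to ZNF711 on every X copy of the control cells is argued against, since APOOL between them stood at 17.0 TPM in the lower shControl library. This rests on 1 gene, and a deletion on only some X copies was not tested. Whether the shSASH1 libraries hold cells of another line is not settled by the bounds set beforehand. EGFR differed by 0.97, within the bound of 1. RB1, reported as deleted in this line, was above the bound of 1 TPM in both groups, at 1.41 TPM in shControl and 2.19 TPM in shSASH1. Its difference did not pass (log2 change 0.40, limma adjusted p = 0.201), so the breach is not particular to shSASH1. SMAD4, also reported as deleted in this line, was at 0.352 TPM in shControl and 0.202 TPM in shSASH1, lower rather than higher.

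The 4630 calls may partly follow segments that differ between the populations, as clones selected separately could. Of the calls 20.54% lay in shifted windows, with an upper 95% bound of 21.7% that treats genes as independent. This share is a lower estimate, since one-sided windows within the shuffle limit are not counted. Chromosome 1 from 20 to 40 Mb, with 86 higher and 14 lower, is such a window, and segments much shorter than 20 Mb can be missed. The share argues only against windows beyond the limit as the source of most calls. The value lies between the bounds of 20% and 50% set beforehand, and that 68.1% of calls kept their sign and passed after centring was weighed with it. A length or GC trend as the whole source is argued against too: after correcting for it 4639 genes were called, 3942 of them calls of the main test with the same sign. The share of higher calls went from 58.6% to 50.1% after this correction. Median-of-ratios scaling, which has no length or GC term, also took the share to 52.1%. The share therefore cannot tell whether the excess of higher calls follows such a trend. Shorter or weaker segments, a clone effect without segments and the depletion itself stay open, because each group may be 1 selected population.

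The downward shift of the oxidative phosphorylation list was also tested against technical causes. After the length and GC correction the list's shift from other genes was -0.32, and after centring on windows -0.34, against -0.34 in the main test, so neither trend accounts for it. The SASH1 depletion and a difference between selected populations are among the explanations left open, and the number of hairpins is not given. Of the ribosomal protein genes 5 were higher and 7 lower.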
